A study of Mus musculus with 9 samples.

How the data were processed

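RNA was measured in 9 libraries of podocytes, the epithelial cells that wrap the glomerular capillaries of the kidney. The cells came from wildtype mice carrying the mTmG reporter and a Cre active in podocytes, so that recombined cells carry green fluorescent protein. Per the labels' protocols, total RNA was taken from GFP-positive cells, ribosomal RNA was depleted with a Ribo-Zero kit, and libraries followed standard Illumina protocols. The labels put 3 libraries in a group given PBS, 3 in a group 9 days after a treatment abbreviated ADR, and 3 in a group 14 days after it. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries.

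The values are FPKM (fragments scaled to transcript length and to the number of mapped fragments), deposited by the authors as a table with 1 column per library. The submitters' processing notes name Bowtie 0.12.7, Cufflinks and the mouse build mm9, without roles. The version of Cufflinks, the annotation, the use of strand and the treatment of reads that map to several places are not given in the sources used here. Values of paralogs, histone and ribosomal protein genes with near-identical copies, and overlapping genes are therefore uncertain. The table holds 23813 rows with 23309 symbols, of which 260 stand on more than 1 row. The row with the highest mean was kept for each symbol. Columns headed control were matched to the PBS libraries by their replicate number.

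Column totals ran from 572787 to 723288 FPKM, so no common total had been imposed. Read counts were not used here. Where a low value is a whole multiple of what 1 read is worth, the most frequent ratio between libraries over genes under 0.3 FPKM estimates their relative depth. Against PBS replicate 2, set to 1, that estimate was 1.085 and 1.082 for the other PBS libraries. It was 0.786, 0.889 and 0.872 on day 9 and 0.239, 0.460 and 0.569 on day 14. The day 14 libraries thus had the lowest depth, and no counting interval can be given for any value. Among 3049 genes with a median of at least 20 FPKM, 16 are listed at 0 in some library, 12 of them small RNA genes. Malat1 is listed at 0 in ADR_D14 replicate 3 and between 1700 and 10638 FPKM elsewhere, so a 0 can be a failed estimate.

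Genes with at least 1 FPKM in at least 3 of the 9 libraries were tested (9788 genes, with 13521 symbols left untested). The test was limma 3.58.1 in R 4.3.3 with a variance trend, on log2(FPKM + 1), with all 9 libraries in the fit and the group as the only term. It was two-sided, with Benjamini-Hochberg adjustment within each comparison, and genes with an adjusted p under 0.05 are said to have passed the test. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Alternative scalings move the median of all genes by over 0.1, so each log2 change is given relative to the median change of all genes tested. That median was 0.04 on day 9 against PBS, −0.15 on day 14 against PBS and −0.22 on day 14 against day 9. Tests used the values as deposited.

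Before the data were examined, 32 gene lists were fixed: podocyte programmes, pathways, markers of other kidney cells and technical lists. Of these, 28 with at least 5 tested members entered limma's camera test with a preset correlation of 0.01, adjusted over the 28 lists. Camera with a correlation estimated from the data and fry were run beside it. The 13 protein genes of the mitochondrial genome were not matched in the table. A list of 14 red cell markers had 4 tested members, and lists of sex-linked genes and of abundant noncoding RNAs were read per library. The rule for named genes was fixed at the same time. It takes up to 10 genes per direction and comparison with the largest change among those that passed the test without overlap between groups and reached a mean of 5 FPKM, up to 4 members per list with the smallest p, and a fixed set of podocyte and injury genes. From the genes this rule gave, those printed were chosen to keep the text short after their values were seen. Genes outside the rule, such as Eif2s3y, were also chosen then.

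Alternatives fixed at the same time were another pseudocount (0.1), other filters, scalings and variance models, small RNA genes left out, duplicate symbols summed, only the groups compared, the replicate number as a block, other thresholds, and each library left out in turn. Alternatives chosen after seeing the data were the removal of the libraries with markers of other kidney cells, alone and with the library high in red cell markers, a term for Y-linked transcripts, libraries of 1 such class alone, and removal of a trend on transcript length and GC content. Lengths and GC shares were those of the longest GENCODE M21 transcript of each symbol, matched for 99.4% of the genes tested. The transcript that the cells express can be shorter. That annotation is for a later build than mm9, so no coordinates are given. The fit was tested on simulated data with 200 changed genes. For day 9 against PBS it recovered 12%, 54%, 82% and 92% of genes changed by 1, 2, 3 and 4 on the log2 scale. For day 14 against PBS the shares were 16%, 54%, 84% and 94%, and for day 14 against day 9 they were 14%, 60%, 86% and 96%. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.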

Results

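The series profiled RNA of mouse podocytes during injury, and its title names the transcription factor WT1 and a repair response. Podocytes were collected from mice given PBS and from mice 9 and 14 days after ADR, with 3 libraries in each group. Between 8629 and 10474 genes reached 1 FPKM per library. The relative depth estimated from the values was 0.239 to 0.569 of that of PBS replicate 2 in the day 14 libraries and 0.786 to 1.085 in all others.

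Wt1 was at 68.8 ± 7.75 FPKM with PBS, 65.2 ± 33.5 on day 9 and 23.3 ± 13.9 on day 14 (mean ± SD, n = 3). Markers of other kidney cells stood out in ADR_D9 replicate 3 and ADR_D14 replicate 1. In each of these libraries, 20 of 23 endothelial markers exceeded 4 times the highest PBS library and reached at least 1 FPKM. Emcn, an endothelial sialomucin, was at 424 and 244 FPKM there, against at most 0.527 with PBS. ADR_D14 replicate 1 also carried 20 of 23 proximal tubule markers, 17 of 21 markers of the distal tubule, loop and duct, and 17 of 27 leukocyte markers above that bound. ADR_D9 replicate 3 carried 11 of 19 mesangial, 12 of 21 distal tubule and 14 of 27 leukocyte markers above it. Of the red cell markers, Hba-a2 and Hbb-b2, which encode globins, were highest in ADR_D9 replicate 1 (267 and 280 FPKM), at 125 and 118 in ADR_D9 replicate 3 and at 17.6 and 38.2 in ADR_D14 replicate 1, against at most 5.04 and 0.343 with PBS. Y-linked transcripts were present in all PBS libraries, in ADR_D9 replicate 1 and in ADR_D14 replicate 2, and near absent in the other 4 libraries. Eif2s3y, for example, ranged from 31.6 to 60.3 FPKM in the former and from 0 to 0.777 in the latter.

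**Figure D1:**
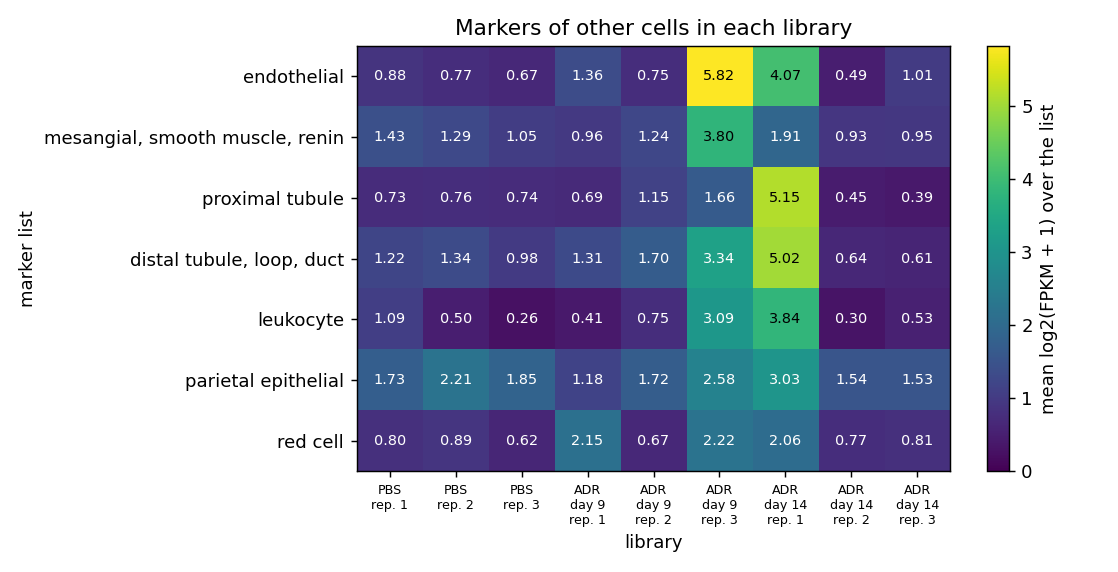
Mean log2(FPKM + 1) over each list of markers of other cells (rows) in each of the 9 libraries (columns, with the group and replicate). The endothelial row reads 5.82 in ADR_D9 replicate 3 and 4.07 in ADR_D14 replicate 1, and at most 1.36 elsewhere. The red cell row reads 2.15 in ADR_D9 replicate 1, 2.22 in ADR_D9 replicate 3 and 2.06 in ADR_D14 replicate 1, and at most 0.892 elsewhere.

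The first comparison asked how podocytes 9 days after ADR differed from PBS. Of 39 podocyte structure genes and 19 podocyte transcription factors, 0 passed limma. Synpo, which encodes the actin-binding protein synaptopodin, was at 116 ± 17.2 FPKM against 38.6 ± 12.7 (log2 change 1.57 ± 0.40 SE, higher in 3 of 3 libraries). Tdrd5, Foxc2 and Crb2 had log2 changes of 1.41, 1.92 and 1.21, each with 3 of 3 libraries above all PBS libraries. They were named because they had among the smallest p of their lists, which favours such a separation. Foxc2 is a forkhead factor needed for podocyte development and Crb2 a slit diaphragm component. Of 26 targets of p53, the factor that responds to DNA damage, 0 passed limma either. Cdkn1a, a cell cycle inhibitor, was at 69.3 ± 65.7 FPKM against 439 ± 140, and Ccng1, a cyclin induced by p53, at 72.6 ± 42.1 against 315 ± 175. Their log2 changes were −3.65 ± 1.43 and −2.12 ± 0.83 (SE), and all day 9 libraries lay below all PBS libraries for both. With 1 library left out Cdkn1a ranged from −4.67 to −2.13.

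No gene passed the limma test on day 9 (0 of 9788, smallest adjusted p = 0.9999). At an unadjusted p under 0.05 there were 304 genes, 186 higher and 118 lower. The Wt1 log2 change was −0.28 ± 0.52 (SE), with ADR_D9 replicate 3 at 26.7 FPKM and the other day 9 libraries at 87.5 and 81.3. Without that library the change was 0.28. Nphs1 (nephrin) and Podxl (podocalyxin) had log2 changes of 0.36 and 0.50, neither past the test. Cd44 and Ezh2 averaged 0.810 and 0.686 FPKM with PBS and had log2 changes of 0.13 and 0.14 on day 9.

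By camera, 10 of 28 lists passed on day 9, 9 of them described here, although none of their members did over all genes or adjusted over the list alone. The p53 target list had the smallest p (median log2 change −1.07, 24 of 26 members below the median of all genes, adjusted p = 5.76e-10, and adjusted p = 0.593 with an estimated correlation). It includes Sesn2 and Eda2r at −1.96 and −3.35. The podocyte structure list had a median of 0.23 with 25 of 39 members above the median gene (adjusted p = 0.0166, and adjusted p = 0.75 with an estimated correlation). The median change was −0.52 for NF-kB targets and cytokines, which include Nfkb2 at −0.80, Cxcl10 at −1.77 and Tnfaip3 at −1.17. Medians were −0.43 for fibrillar matrix and mesenchymal genes (Timp1 −2.08, Lox −1.30, Ctgf −1.41), −0.40 for complement (C1ra −1.28, C1s −1.23), −0.42 for replication-dependent histones (Hist2h2aa1 −1.02, Hist1h1d −0.82) and −0.30 for parietal epithelial markers (Cldn1 −0.99, Aldh1a1 −3.04). Also past the test were endothelial markers at 2.69, with Emcn at 3.39, Plvap at 2.81 and Esam at 3.21, and distal tubule markers at 1.20, with Aqp2 at 3.38 and Aqp3 at 3.08. No list passed with an estimated correlation (smallest adjusted p = 0.312) or by fry (smallest adjusted p = 0.648).

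Of the lists described, each except the p53 targets failed camera without at least 1 library. Without ADR_D9 replicate 1, podocyte structure (0.06, adjusted p = 0.734), matrix (−0.08, 0.663), NF-kB (−0.27, 0.258), complement (−0.22, 0.121) and parietal markers (0.04, 0.354) failed, and without ADR_D9 replicate 3 histones (−0.17, 0.352), endothelial (0.52, 0.352) and distal tubule markers (0.30, 0.508). Most failed without other libraries too, and without PBS replicate 1 only 4 lists passed. Of the 9 fits that left out 1 library, distal tubule markers passed in 4, complement in 5, podocyte structure and parietal markers in 6, matrix, NF-kB and histones in 7 and endothelial markers in 8. Genes moved as well: without ADR_D9 replicate 1, Cxcl10 was at −0.81, Lox at −0.77, C1ra at −0.79 and C1s at −0.67. Without ADR_D9 replicate 3, Hist1h1d was at −0.42, Emcn at 0.96, Plvap at 1.04, Esam at 0.82, Aqp2 at 1.95 and Aqp3 at 1.77. The p53 medians without each library in turn ran from −1.23 to −0.65.

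**Figure D2:**
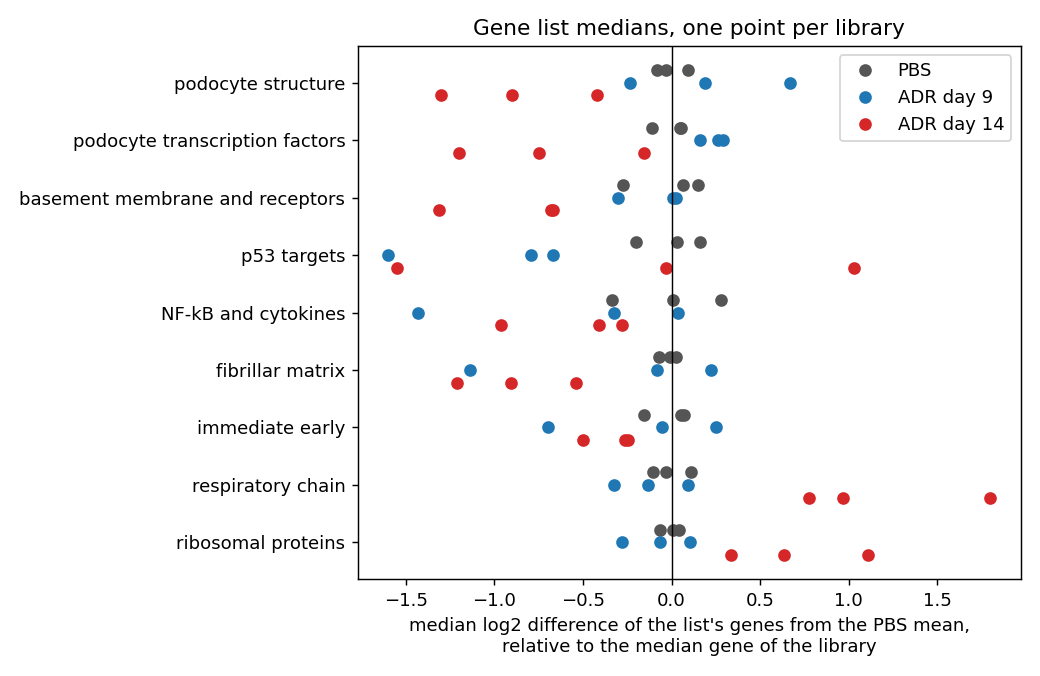
Median log2 difference of each list's tested genes from the PBS mean, relative to the median gene of the library (x axis), for 9 lists (y axis) and 9 libraries (points, coloured by group). The p53 targets lie at −1.60, −0.79 and −0.67 on day 9 and spread from −1.55 to 1.03 on day 14, and the respiratory chain list lies at 0.77 to 1.80 in the day 14 libraries.

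The second comparison set day 14 against PBS. Of 39 podocyte structure genes, 12 fell. Among them Pdpn, which encodes podoplanin of foot processes, fell from 323 ± 25.5 to 60.1 ± 40.4 FPKM (log2 change −2.62 ± 0.62 SE, adjusted p = 0.0231 by limma). Dag1, the laminin receptor dystroglycan, fell from 134 ± 22.4 to 24.4 ± 4.60 FPKM (−2.27 ± 0.25, adjusted p = 0.00905 by limma), and both lay below all PBS libraries in 3 of 3 libraries. Of 36 nuclear-encoded respiratory chain genes, 14 rose, with Ndufv2 of complex I going from 217 ± 35.1 to 776 ± 193 FPKM (1.96 ± 0.26, adjusted p = 0.00994 by limma). Wt1 lay lower in 3 of 3 libraries (−1.52 ± 0.52) and did not pass the test (adjusted p = 0.0563 by limma).

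In all, 1670 genes passed, 619 higher and 1051 lower (37.1% higher). The balance depended on scaling, with 784 higher and 848 lower after median-of-ratios scaling, 710 and 755 after quantile normalization, 408 and 1680 with a common total, and 420 and 1626 with small RNA genes left out as well. The largest increases by the naming rule included Glrx5, which acts in mitochondrial iron-sulfur cluster assembly (3.48), Ndufa12 of complex I (2.72) and Acot13, an acyl-CoA thioesterase (2.68). They also included the histocompatibility genes H2-T10 (0.886, 7.48 and 0.354 FPKM with PBS, 10.3, 41.4 and 49.5 on day 14) and H2-Q7 (26.5, 23.5 and 14.5, then 90.3, 286 and 112). The largest decreases included Tenc1, which encodes tensin 2 (−3.43), Bag6, a protein quality control chaperone (−3.05), Bcam, a laminin receptor (−2.75), and Pdpn. For each of these genes 3 of 3 day 14 libraries lay beyond all PBS libraries, which the naming rule required, so it adds no support.

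The podocyte structure genes had 12 lower and 0 higher (15 and 0 adjusted over the list alone), and the list's median was −0.94 (camera adjusted p = 4.41e-05, and adjusted p = 0.829 with an estimated correlation). Besides Pdpn the lower ones included the motor protein gene Myo1e (−1.72), the scaffold gene Iqgap1 (−2.02) and Rhpn1 (−1.83). Synpo, Podxl and Nphs1 did not pass, at −0.99, −0.45 and −0.37. Of 19 podocyte transcription factors, 2 fell, among them Nfia (−1.16), and the list did not pass (median −0.62, adjusted p = 0.0709). Over all genes 1051 of 9788 fell, which is about the same share. Lmx1b and Tcf21 did not pass, at −0.88 and −0.67. Of 20 genes of the glomerular basement membrane and its receptors, 8 fell and 0 rose (9 and 0 adjusted over the list alone; median −0.98, adjusted p = 0.000335, and adjusted p = 0.765 with an estimated correlation). Examples are the laminin chain gene Lamb2 (−2.33), the integrin gene Itga3 (−1.77) and Parva, which encodes an integrin-linked adaptor (−1.71).

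In the respiratory chain list 14 rose and 1 fell (20 and 1 adjusted over the list alone; median 1.18, adjusted p = 3.78e-07, and adjusted p = 0.829 with an estimated correlation). The median of this list against the PBS mean was 1.80 in ADR_D14 replicate 1, which held markers of other kidney cells, and 0.774 and 0.967 in replicates 2 and 3. Sdhb and Cox4i1 rose (1.60 and 2.36), and Sdha, the flavoprotein subunit of complex II, fell (−1.30). Of 33 ribosomal protein genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.56, adjusted p = 0.00472, and adjusted p = 0.829 with an estimated correlation). Rps19, Rps14 and Rpl37 rose (1.58, 1.39 and 1.19) and Rpl4 fell (−1.10). Rps14 and Rpl37 were low, at most 3.92 and 3.19 FPKM with PBS. Both were highest in ADR_D14 replicate 1 (15.6 and 9.66 FPKM), the library of lowest depth. Fry asks whether a list's genes move on balance one way from 0, as deposited and not relative to other genes. By fry, podocyte structure (adjusted p = 0.0483), podocyte transcription factors (0.0483) and basement membrane (0.00501) passed and the respiratory chain (0.0596) and ribosomal (0.136) lists did not.

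**Figure D3:**
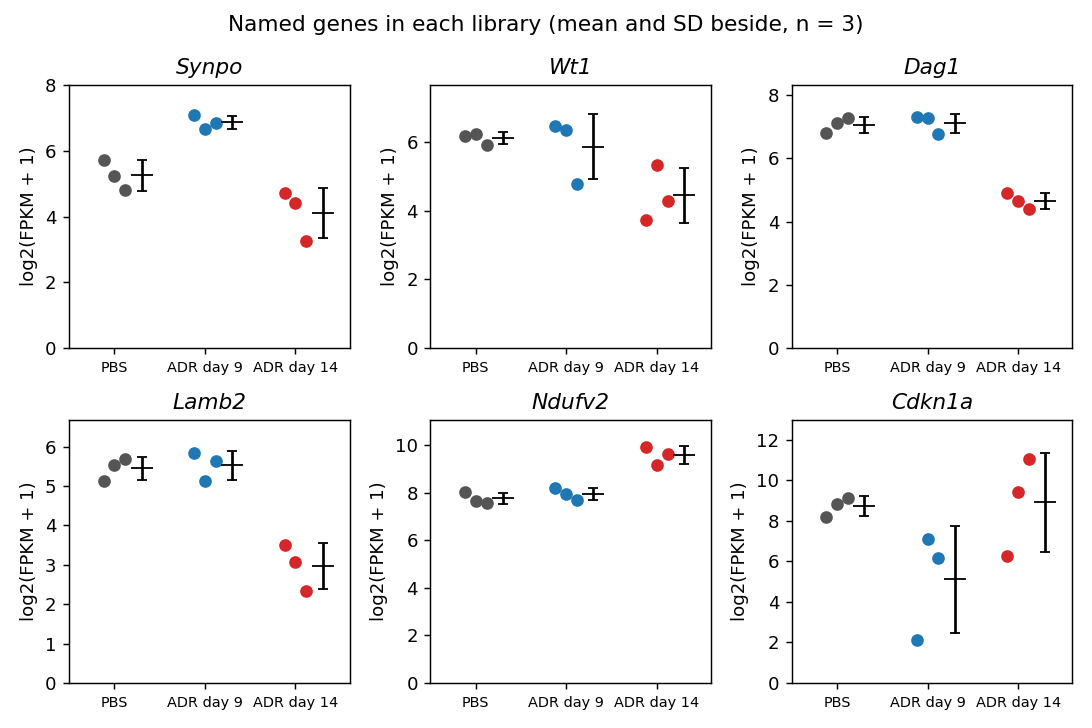
Values of 6 genes on the log2(FPKM + 1) scale (y axis) in each library (points) of the 3 groups (x axis), with the group mean and SD (n = 3) as a bar and whiskers. Dag1 and Lamb2 lie lower and Ndufv2 lies higher in all day 14 libraries than in any PBS or day 9 library, and Cdkn1a ranges from 76.8 to 2159 FPKM within day 14.

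Changes on day 14 followed transcript length. Across genes, the Spearman correlation of the log2 change with transcript length was −0.331 on day 14 and 0.073 on day 9. Genes are not independent replicates, so no p is given. The median transcript length was 4699 bases in the podocyte structure list, 5766 in the basement membrane list, 1591 in the respiratory chain list and 1120 in the ribosomal list, against 3178 over all genes tested. With the trend on length and GC content removed, 712 genes passed, 398 higher and 314 lower, and 34.0% of the original 1670 did so in the same direction. Medians were then −0.73 for podocyte structure, −0.48 for the basement membrane, 0.39 for the respiratory chain (adjusted p = 0.00978 each by camera) and 0.07 for ribosomal proteins (adjusted p = 0.922). This removal also took out the overall shift of each library, so it rescaled the values as well. The balance of higher and lower genes after it therefore cannot be credited to length and GC content alone. Dag1 still passed (−1.75). Of the genes named above, Itga3 (−1.03), Rhpn1 (−1.23), Nfia (−0.99), Acot13 (1.83), Rps14 (0.64) and Rpl37 (0.40) no longer did (adjusted p from 0.0590 to 0.274 by limma), and Nphs1 and Podxl stood at 0.35 and 0.04. By limma, 0 genes passed with a term for Y-linked transcripts (2411 at an unadjusted p under 0.05, smallest adjusted p = 0.0687) and 0 without PBS replicate 2 (2336, smallest adjusted p = 0.0660). With the term, log2 changes were still −2.13 for Dag1, −2.09 for Lamb2, 1.93 for Ndufv2 and −2.98 for Tenc1. The calls of these genes were thus lost with changes about as large. Others shrank more, with Rhpn1 at −1.21, Itga3 at −1.31, Iqgap1 at −1.57 and Bcam at −2.09. Of podocyte genes that had not passed, Synpo was at −0.70, Lmx1b at −0.60, Podxl at −0.17, Tcf21 at −0.03 and Nphs1 at 0.10. The count was 157 without PBS replicate 3, 1096 without ADR_D9 replicate 2 and 551 with only the PBS and day 14 libraries in the fit. Without the pair of libraries that held markers of other kidney cells, 2187 genes passed, which included 88.1% of the original genes, and Wt1 passed (−1.14, adjusted p = 0.0275 by limma). With the term for Y-linked transcripts Wt1 was at −0.75 (adjusted p = 0.283 by limma), and its adjusted p ran from 0.0275 to 0.283 over the alternatives, leaving aside array weights, whose estimate did not converge (adjusted p = 0.00883). No named gene passed in all fits that left out 1 library, and Nfia, Rpl37 and Rpl4 passed in 4 of 9 and Pdpn and Rps14 in 6 of 9.

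**Figure D4:**
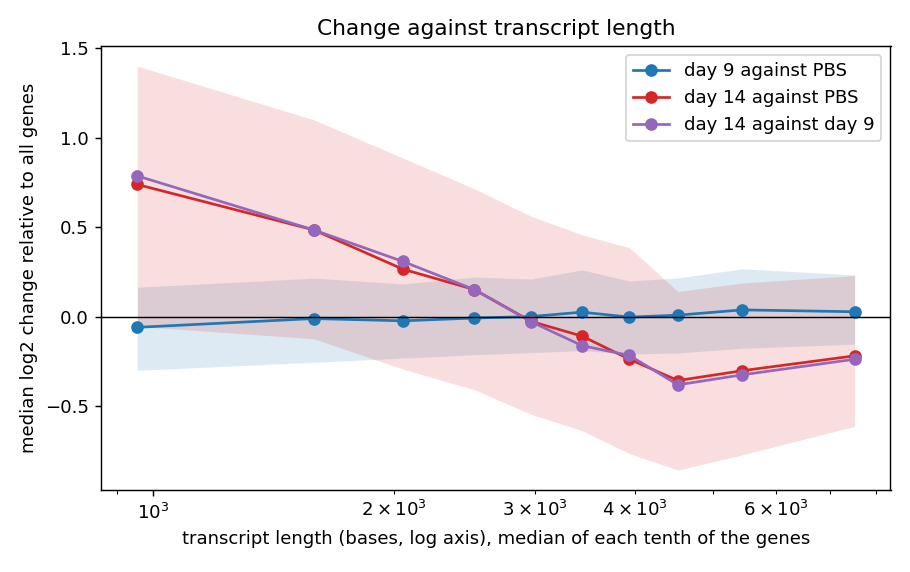
Median log2 change relative to all genes (y axis) against transcript length in bases (x axis, log scale) for 10 bins of genes ordered by length, with quartiles shaded for the comparisons against PBS. The day 14 medians against PBS go from 0.74 in the bin of shortest transcripts to −0.22 in that of the longest, with a lowest value of −0.36, and the day 9 medians stay between −0.06 and 0.04.

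The third comparison asked what differed between day 14 and day 9, and so tests the difference between the time points directly. Of 39 podocyte structure genes, 17 were lower on day 14. Among them Synpo fell by 2.53 ± 0.40 (SE, adjusted p = 0.00999 by limma). Vegfa, the vascular growth factor that podocytes secrete, fell from 814 ± 273 to 114 ± 53.7 FPKM (−2.65), and Npnt, which encodes the basement membrane protein nephronectin, from 878 ± 179 to 139 ± 77.1 FPKM (−2.63). Atp1b1, a subunit of the sodium pump, rose from 38.9 ± 26.9 to 647 ± 464 FPKM (4.28), and Lgals3, which encodes galectin-3, from 28.7 ± 13.4 to 349 ± 237 FPKM (3.64). With PBS, Atp1b1 was at 106, 336 and 102.5 FPKM and Lgals3 at 208, 84.1 and 14.5. For both, the PBS and day 14 libraries overlapped, so a rise above PBS is not shown. For Synpo, Vegfa, Npnt, Atp1b1 and Lgals3, 3 of 3 day 14 libraries lay beyond all day 9 libraries. The naming rule required this for Atp1b1 and Lgals3, so it adds no support there.

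By limma, 1536 genes passed, 559 higher and 977 lower (36.4% higher). The split was 706 and 742 after median-of-ratios scaling, 677 and 535 after quantile normalization, 390 and 1844 with a common total, and 377 and 1900 with small RNA genes left out as well. Prss23, a serine protease gene, was among the largest increases (3.55), and Thbd (thrombomodulin) and Sema3g, a secreted semaphorin, among the largest decreases (−3.81 and −3.34). Prss23 was at 21.2, 21.3 and 16.3 FPKM with PBS and at 10.7, 24.6 and 80.7 on day 14. Thbd was at 6.53, 5.06 and 4.65 FPKM with PBS and at 5.26, 0.925 and 1.51 on day 14. Both thus overlapped between PBS and day 14. Wt1 (−1.21), Nphs1 (−0.70), Tcf21 (−0.80) and Cdkn1a (4.03 ± 1.43) did not pass. Cdkn1a was at 76.8, 681 and 2159 FPKM in the day 14 libraries. Cd44 and Ezh2 did not pass in any comparison.

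The podocyte structure genes had 17 lower and 0 higher (21 and 0 adjusted over the list alone; median −1.08, camera adjusted p = 7.51e-07, and adjusted p = 0.819 with an estimated correlation). The lower ones included Podxl (−0.92), Myo1e (−1.82) and Iqgap1 (−2.25). Of 19 podocyte transcription factors, 3 fell, among them Foxc2 (−2.65) and Lmx1b (−1.70), with 5 adjusted over the list alone (median −0.63, adjusted p = 0.015, and adjusted p = 0.819 with an estimated correlation). Of 20 basement membrane and receptor genes, 8 fell (11 adjusted over the list alone; median −0.95, adjusted p = 0.00116, and adjusted p = 0.819 with an estimated correlation), among them Dag1, Lamb2 and Parva (−2.25, −2.35 and −1.68). Of 36 respiratory chain genes, 16 rose and 1 fell (23 and 1 adjusted over the list alone; median 1.39, adjusted p = 1.44e-09, and adjusted p = 0.819 with an estimated correlation), with Sdhb at 1.73, Ndufb9 at 2.71 and Sdha at −1.13. Of 33 ribosomal protein genes, 4 rose (2 adjusted over the list alone; median 0.67, adjusted p = 0.000812, and adjusted p = 0.819 with an estimated correlation): Rps19, Rps16, Rps14 and Rpl37, at 2.34, 1.498, 1.30 and 1.17. Rps14 and Rpl37 were low, at most 4.29 and 3.24 FPKM on day 9. The p53 target list was higher (median 1.04, adjusted p = 0.00139, and adjusted p = 0.820 with an estimated correlation) with 2 members up and 1 down (1 and 1 adjusted over the list alone). Of 26 members that is few, since 559 of 9788 genes rose and 977 fell over all genes. Bax, which promotes apoptosis, and Dcxr, a reductase gene, rose (1.62 and 1.59), and Ddb2, a nucleotide excision repair gene, fell (−0.89). Of the genes named for this comparison, Bax and Podxl passed in 1 of the 9 fits that left out 1 library, Rps14 and Rpl37 in 2, Lgals3 in 3, Rps16 and Ddb2 in 5, Thbd in 6, Lmx1b and Prss23 in 7 and the others that had passed in all 9. Dcxr passed in 2 of 6, since it fell below the filter when a day 14 library was left out. With the length and GC trend removed, Podxl (−0.39), Lmx1b (−0.83), Lgals3 (3.11), Bax (1.03), Dcxr (0.76), Rps16 (0.71), Rps14 (0.50) and Rpl37 (0.31) no longer passed (adjusted p from 0.0852 to 0.497 by limma). With this trend removed the ribosomal list (median −0.017, adjusted p = 0.925 by camera) and the podocyte transcription factors (−0.39, 0.0866) did not pass either. By fry podocyte structure (adjusted p = 0.0182), podocyte transcription factors (0.00932), basement membrane (0.00457) and the respiratory chain (0.0338) passed and the p53 (0.339) and ribosomal (0.114) lists did not.

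Fewer genes passed without certain libraries: 0 without all 3 libraries with red cell or other-cell markers (limma, 2067 at an unadjusted p under 0.05, with a lone day 9 library left), 407 without ADR_D9 replicate 3, 501 without ADR_D9 replicate 1, 639 without ADR_D9 replicate 2 and 737 without PBS replicate 2. The count was 556 with the length and GC trend removed and 431 with only the groups compared in the fit. It was 1292 with a term for Y-linked transcripts, and 0 by limma within the 4 libraries lacking them (1175 at an unadjusted p under 0.05). The p53 list did not pass camera without ADR_D14 replicate 3 (median 0.59, adjusted p = 0.286). The podocyte transcription factors did not pass without ADR_D14 replicate 1 (−0.77, adjusted p = 0.0812) or replicate 3 (−0.79, 0.0584), nor the basement membrane list without ADR_D14 replicate 1 (−0.88, 0.0565).

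No gene passed both on day 9 and on day 14 against PBS, since none passed on day 9. Across genes, the log2 changes of these comparisons correlated at r = 0.351, against 0.502 simulated for unchanged groups sharing the PBS libraries, with a covariance of 0.174 against a simulated 0.166. Their signs matched in 59.6% of genes, against 66.7% simulated. The comparisons of day 14 with PBS and with day 9 shared 461 higher and 728 lower genes and none in opposite directions. Both comparisons use the same day 14 libraries, so this overlap is not independent evidence.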

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

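The length and GC tests, the count of endothelial markers, the comparison with the other ADR libraries and both p53 tests were chosen after the results were seen. The test of depth and the rank correlation of the endothelial markers were chosen before.

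These results stand out because the change against PBS differed between day 14 and day 9 by limma or camera, with adjusted p under 0.05 for the difference itself. Among lists the difference, day 14 minus day 9 as a median log2 change, was −1.08 for podocyte structure, −0.63 for podocyte transcription factors, −0.95 for the basement membrane and its receptors, 1.04 for p53 targets, 1.39 for the respiratory chain and 0.67 for ribosomal proteins. With an estimated correlation none of these lists passed (adjusted p of 0.819 or 0.820 by camera). With the length and GC trend removed, the ribosomal (−0.017, adjusted p = 0.925) and transcription factor (−0.39, 0.0866) differences no longer passed, and that of the respiratory chain was 0.55. Of the genes that follow, Bax and Podxl passed in 1 of the 9 fits that left out 1 library, Crb2, Rps14 and Rpl37 in 2, Actb and Lgals3 in 3, Wasl in 4, and Bcam, Ddb2, Prdx1, Rbpj and Rps16 in 5. Acot13, Bag6 and Thbd passed in 6, Lmx1b and Prss23 in 7, Cox4i1 and Egr1 in 8, the others in all 9, and Dcxr in 2 of 6. With the length and GC trend removed some no longer passed though the difference stayed about as large: Wasl (−1.12), Lgals3 (3.11), Bcam (−1.82) and Rbpj (−0.70). Others that no longer passed were smaller by more: Acot13 (1.68), Bag6 (−1.04), Bax (1.03), Crb2 (−0.36), Dcxr (0.76), Egr1 (−1.18), Itga3 (−0.93), Lmx1b (−0.83), Podxl (−0.39), Prdx1 (1.195), Rhpn1 (−1.39), Rpl37 (0.31), Rps14 (0.50) and Rps16 (0.71). Podocyte and basement membrane genes that were lower on day 14 than on day 9, by the log2 difference, were Sema3g (−3.34), Foxc2 (−2.65), Vegfa (−2.65), Npnt (−2.63), Synpo (−2.53), Lamb2 (−2.35), Iqgap1 (−2.25), Dag1 (−2.25), Bcam (−2.21), Rhpn1 (−2.16), Myo1e (−1.82), Itga3 (−1.79), Tdrd5 (−1.72), Lmx1b (−1.70), Parva (−1.68), Crb2 (−1.13) and Podxl (−0.92). Other genes lower by this difference were Thbd (−3.81), Tenc1 (−2.76), Egr1 (−2.03), Bag6 (−1.94), Actb (−1.35), Wasl (−1.18), Sdha (−1.13), Ddb2 (−0.89) and Rbpj (−0.85). Genes higher by it were Atp1b1 (4.28), Lgals3 (3.64), Prss23 (3.55), Ndufa12 (2.92), Ndufb9 (2.71), Acot13 (2.63), Cox4i1 (2.49), Rps19 (2.34), Atg3 (2.31), Ndufv2 (1.85), Sdhb (1.73), Prdx1 (1.68), Bax (1.62), Dcxr (1.59), Rps16 (1.498), Rps14 (1.30) and Rpl37 (1.17).

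The day 14 changes followed transcript length, with lower values for long transcripts in each day 14 library (Spearman −0.352 to −0.218 against PBS, slopes on log2 length −0.349 to −0.263). PBS replicate 1 showed the same ranking against the other PBS libraries (−0.245) with a smaller slope (−0.0984). Lower depth should act on genes near the floor. The slope on log2 length at a mean of at least 20 FPKM was 1.32 times that below it (−0.368 ± 0.019 SE against −0.279 ± 0.011 SE). The trend was thus not confined to low genes. The log2(FPKM + 1) scale shrinks the changes of low genes, which itself raises this ratio, so the test cannot decide about depth. With the trend on length and GC content removed, 34.0% of the genes that had passed against PBS still passed in the same direction, and the podocyte structure median was −0.73. The trend as fitted thus did not account for all of either. It was fitted on the longest transcript of each symbol, so its removal can be incomplete and a larger part stays open. The ribosomal median went from 0.56 to 0.07 and no longer passed, the respiratory chain median from 1.18 to 0.39 and the basement membrane median from −0.98 to −0.48, so a length effect stays open for the first and for part of the others. Whether RNA quality or library preparation gave the trend, or a change in the cells on day 14 did, was not tested.

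Markers of other kidney cells were high in ADR_D9 replicate 3 and ADR_D14 replicate 1, where Pecam1 was at 272 and 44.9 FPKM and Egfl7 at 1444 and 274. A candidate explanation is other kidney cells or their RNA in these libraries, although the selection of GFP-positive cells is meant to exclude such cells. The test chosen first asked whether the endothelial markers ranked alike in both (Spearman 0.916 over 23 markers), but the PBS libraries ranked them alike too (0.791 to 0.863), so it could hardly have come out otherwise and decides nothing. A second test, chosen after that result was seen, found 82.6% of the markers above 4 times the highest PBS library and at 1 FPKM or more in both. These libraries had been singled out by that same count, so it decides nothing either. Lists that this count did not use were also high. Above the same bound were 20 of 23 proximal tubule and 17 of 27 leukocyte markers in ADR_D14 replicate 1, and 5 of 23 and 14 of 27 in ADR_D9 replicate 3. The rise was thus not of endothelial genes alone, and other cells or their RNA stay open as the explanation. A rise of endothelial genes in podocytes of all ADR libraries is argued against by the remaining 4 ADR libraries. In each, at most 8.70% of the endothelial markers exceeded 4 times the highest PBS library and reached 1 FPKM. A rise in the podocytes of ADR_D9 replicate 3 and ADR_D14 replicate 1 alone stays open.

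The p53 target list was lower on day 9, with medians against the PBS mean of −1.60, −0.79 and −0.67 in the libraries. With a term for Y-linked transcripts the median was −1.31. All PBS libraries had these transcripts, but on day 9 only ADR_D9 replicate 1 did, at a list median of −1.60. The fit with this term leans on that library, so it cannot decide whether an imbalance of sex contributed. Other cells in ADR_D9 replicate 3 are unlikely to be the whole cause, since the list median was −1.27 without both libraries that held their markers. Lower p53 target transcripts after ADR, or higher ones in the PBS libraries from handling, stay open and were not tested. The call was lost with an estimated correlation (adjusted p = 0.593 by camera).

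With 3 libraries against 3 there are 10 splits, which cannot give a share under 0.1. The gene counts by limma were 0 for day 9 against PBS (304 at an unadjusted p under 0.05, highest other split 1, and all 10 splits gave as many), 1670 for day 14 against PBS (highest other 1, and 1 split, the real one, gave as many) and 1536 for day 14 against day 9 (highest other 2, and again 1 split). A count of 0 is matched by every split, so the day 9 gene split tells nothing. The list counts by camera were 10, 4 and 6, with highest other splits of 15, 8 and 13, and 6, 9 and 8 of the 10 splits gave as many lists. The number of lists that passed is therefore weak evidence of a difference between groups.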

How the results depend on the processing

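The removal of both libraries with other-cell markers, alone or with the library high in red cell markers, the term for Y-linked transcripts (sex term), the fits on libraries with or lacking Y-linked transcripts alone and the removal of the length and GC trend were chosen after seeing the data. Over 84 list results, 2178 of 2361 values kept their side of the threshold (169 of them, short of it, with the other sign), 102 were weaker, 71 stronger and 10 reversed. Over 123 named gene results the counts were 2905 of 3428 (21 with the other sign), 486, 37 and 0. The cause was not tested for any change below, except where fewer libraries or genes entered the fit.

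With no low-value filter, limma gave 2, 997 and 881 genes (day 9 against PBS, day 14 against PBS, day 14 against day 9), 9 lists for day 14 against PBS and 2 genes shared by days 9 and 14. Array weights gave 182, 5229 and 3248 genes, 91 shared and 69 that went back by day 14, with Wt1 on day 14 at −0.90. Their estimate did not converge and gave PBS replicate 2 a weight of 56.6, against at most 2.04 elsewhere. At an adjusted p under 0.10 there were 2691 and 2673 genes in the day 14 comparisons, and Wt1 passed at −1.52. With only the 2 groups in the fit there were 1, 551 and 431 genes. Estimated correlation gave 0, 0 and 0 lists and fry 0 on day 9. Wt1 on day 14 passed at −1.58 each with a mean FPKM of at least 5, a common total, and small RNA genes left out, and at −1.14 with both marker-bearing libraries left out. It did not pass with the sex term (−0.75, adjusted p = 0.283 by limma), in libraries with Y-linked transcripts alone (−0.62) or with length and GC removed (−1.38). With all libraries with other-cell or red cell markers left out there were 0, 1590 and 0 genes (70, 3457 and 2067 at an unadjusted p under 0.05) and Wt1 passed at −1.15, with a lone day 9 library in the fit. The replicate block gave 0, 1301 and 1200 genes, but the numbers do not pair the libraries, since 2 of 9 were most alike with their own number.

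For day 14 against PBS the sex term gave 0 genes (2411 at an unadjusted p under 0.05, smallest adjusted p = 0.0687 by limma), with Dag1 (−2.13), Ndufv2 (1.93), Atg3 (2.27) and Sdha (−1.51) changed about as much as before. Others changed less than before, such as Rhpn1 (−1.21), Itga3 (−1.31) and Iqgap1 (−1.57). For day 14 against day 9 it gave 1292 genes. Libraries with Y-linked transcripts alone gave 5, 0 and 0 genes and 2 lists for day 14 against PBS (3241 and 2282 genes at an unadjusted p under 0.05 for the zeros), and libraries lacking them gave 0 for day 14 against day 9 (1175 unadjusted). In these fits a group with a lone library is assumed to vary like the others. Length and GC removal gave 712 and 556 genes.

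Without any one library in turn, genes ranged from 0 to 1, from 0 to 1879 and from 407 to 2131, lists from 4 to 12, 4 to 7 and 4 to 6, Wt1 from −0.55 to 0.28 on day 9 and from −1.97 to −1.14 on day 14 against PBS, shared genes from 0 to 1 and genes that went back stayed at 0. The interferon list on day 9 ranged from −0.55 to 0.24 and reversed without ADR_D9 replicate 1 and with all marker-bearing libraries left out (0.16). Distal tubule markers between days 14 and 9 had a median of −0.18 while their test pointed up, and the median ranged from −2.09 to 1.12. Their test direction alone reversed without ADR_D14 replicate 1 (−2.09) and with both (−1.49) or all marker-bearing libraries left out (−1.97). On day 9 against PBS they reversed with the sex term (−0.56, against 1.20). NF-kB targets reversed between days 14 and 9 in libraries with Y-linked transcripts alone (1.14). With the length and GC trend removed, histones reversed on day 14 (−0.64), and the test direction of ribosomal proteins reversed against PBS (0.067) and against day 9 (−0.017). Low depth on day 14 limits what can be said of low genes.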

Other observations

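Other gene groups held single genes that fell on day 14 against PBS, although their lists did not pass camera. Over all genes 1051 of 9788 fell and 619 rose, so a few such genes in a group are not particular to it. Of 26 immediate early genes, 4 fell and 0 rose, among them Egr1, a growth response factor that went from 1654 ± 150 to 320 ± 157 FPKM (log2 change −2.33, adjusted p = 0.0118 by limma), and Fosb (−2.09). Wasl fell (−2.09), and so did Actb (−2.20), at 958 ± 417 FPKM against 4779 ± 1596. Of 10 Notch pathway genes, 3 fell, among them Lfng, a modifier of Notch receptors (−2.24), and Rbpj, their DNA-binding partner (−1.23). Nfkb2 and Tnfaip3 of the NF-kB list fell (−1.39 and −2.00). Prdx1, a peroxide-reducing enzyme, rose (1.69) and Slc7a11, a cystine transporter, fell (−1.88) among oxidative stress genes. Of 28 autophagy and lysosome genes, 3 rose and 1 fell (3 and 3 adjusted over the list alone), with Atg3 among those that rose (2.32). Once the length and GC trend was removed, Egr1 (−1.58), Fosb (−1.54), Nfkb2 (−0.68), Tnfaip3 (−1.68), Prdx1 (1.26) and Slc7a11 (−1.77) no longer passed (adjusted p from 0.0614 to 0.1 by limma), and Wasl, Actb, Lfng, Rbpj and Atg3 did.

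Among lists that did not pass camera on day 14 against PBS, median log2 changes were −0.75 for fibrillar matrix, −0.72 for complement, −0.69 for Notch, −0.48 for NF-kB targets, −0.36 for immediate early genes, −0.27 for Wnt, −0.19 for endoplasmic reticulum stress, −0.10 for chromatin regulators, 0.15 for interferon response, 0.15 for autophagy and lysosome, 0.31 for BMP and TGF-beta, 0.39 for oxidative stress and 0.41 for cell cycle (smallest adjusted p = 0.0709). The medians were 0.04 for histones, −0.04 for parietal epithelial, −0.18 for mesangial, 1.72 for endothelial, 1.89 for proximal tubule, 1.34 for distal tubule and 1.72 for leukocyte markers (smallest adjusted p = 0.210). The latter 4 rest on ADR_D14 replicate 1, and without it they were 0.21, −0.42, −0.56 and −0.56. Without 1 library or another, Wnt reached 0.03, BMP and TGF-beta 0.02 and cell cycle 0.09. For p53 targets and DNA repair both medians were −0.02, while their tests pointed up (adjusted p = 0.792 each).

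On day 9 against PBS the lists that did not pass camera had medians of 0.27 for podocyte transcription factors, 0.11 for DNA repair, 0.21 for cell cycle, −0.16 for interferon response, −0.16 for the respiratory chain, −0.29 for oxidative stress, −0.02 for autophagy and lysosome, 0.12 for Wnt, 0.45 for BMP and TGF-beta, 0.15 for chromatin regulators, −0.09 for immediate early genes and −0.05 for ribosomal proteins (smallest adjusted p = 0.0775). Medians were 1.06 for mesangial, 0.63 for proximal tubule and 1.61 for leukocyte markers, which rest on ADR_D9 replicate 3 and were −0.24, 0.13 and 0.05 without it. With 1 library left out, cell cycle ranged from −0.22 to 0.49 and BMP and TGF-beta from 0.02 to 1.004. For the basement membrane (0.01) and Notch (0.05) the medians lay above 0 and the tests pointed down, and for endoplasmic reticulum stress the median was 0.01 and the mean −0.05. Between day 14 and day 9 the 22 lists that did not pass had adjusted p of at least 0.142 by camera. By fry, chromatin regulators (median −0.26, adjusted p = 0.0265), endoplasmic reticulum stress (−0.29, 0.0338) and Notch (−0.66, 0.0466) among them passed, each lower on day 14. Fry tests the deposited changes against 0, and the median of all genes was −0.22 in this comparison. A fall beyond that of other genes is therefore not shown for these lists.

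H2-D1, a class I histocompatibility gene, ranged from 164 to 16129 FPKM, with 319, 3659 and 164 in the PBS libraries. Gapdh was listed at 1.49 to 8.56 FPKM. Eda2r, a p53 target, was at 22.6, 24.4 and 23.4 FPKM with PBS, at 0, 6.29 and 1.02 on day 9 and at 1.11, 24.4 and 111 on day 14. Xist was at 0.897 to 2.15 FPKM in the 4 libraries near absent for Y-linked transcripts and at most 0.139 in the others. ADR_D14 replicate 1 had the lowest Spearman correlations with all other libraries across genes (0.656 to 0.775), against 0.897 to 0.965 among PBS libraries, and genes are not independent replicates. These genes were chosen after their values were seen.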
